A study of Homo sapiens with 9 samples.

How the data were processed

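Primary human bronchial epithelial cells were grown on porous inserts with their upper face exposed to air, a culture in which these cells differentiate, and were kept for 24 h with 0, 50 or 100 mM ethanol. The series' design text says that cells came from 3 lots and that RNA with an integrity number of 9.8 was used. RNA was hybridised to Affymetrix human whole-genome arrays, 1 array per sample and 3 arrays per group, 9 in all. Which lot each array holds, and whether replicates came from separate cultures, is not given in the sources used here, so p-values measure the spread between these arrays, part of which may be technical.

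The deposited table holds 54675 probe sets as ratios on a linear scale. Per the labels and the series' design text, the authors imported the scanner files into GeneSpring GX 7.3, applied RMA, and divided each probe set by its median over the untreated arrays. In the deposited values that median was 1, within 0.0015, for 100% of probe sets. The ratio keeps no absolute level, so the brightness behind a value is unknown and no probe set can be called dim. The division also makes the untreated arrays narrower than the ethanol arrays: their interquartile range of log2 ratios was 0.295 ± 0.200 (SD, n = 3), against 0.760 ± 0.131 at 50 mM and 0.830 ± 0.128 at 100 mM. Ratios ran from 0.0102 to 255.9 and 15 cells were empty. The array medians lay between -0.12 and 0.03 on the log2 scale. That RMA was used is taken from the design text and was not shown by the values.

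The ratios were put on the log2 scale with no pseudocount and no further normalization. The 62 Affymetrix control probe sets were left out of the tests, which left 54613. GEO's platform annotation gave 1 gene symbol to 41091 of these, several to 1801 and none to 11721; 41037 of the first kind were matched by gene ID to the RefSeq gene table, and 0 symbols changed. No gene is named from a probe set with several symbols. Levels of 120 probe sets are not given, to protect the donors. For tests on genes, the probe sets of a gene were averaged on the log2 scale, which gave 19774 genes.

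The tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, trend and robust options off, statmod 1.5.0 installed). All 9 arrays entered 1 fit with a mean per group and a shared spread. The 4 contrasts tested were 50 mM minus untreated, 100 mM minus untreated, 100 mM minus 50 mM, and the bend, which is 50 mM minus the mean of untreated and 100 mM; an F test asked for any difference among the 3 groups. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The threshold in the design text, p of at most 0.01 and a 2-fold change, was applied to the limma p-values, since the test behind it is not given in the sources used here. Gene lists fixed before the data were examined, 30 in number with 8 of them for cell types, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Errors of differences are standard errors of the fit.

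Replicates 1, 2 and 3 appear in each group. Deviations from the group means correlated at 0.135 to 0.291 over genes between the 9 pairs of arrays with the same number and at -0.196 to 0.024 between arrays of different numbers, and 9 of 9 arrays correlated best with an array of their own number. The numbers were therefore taken to pair the arrays, from the data and not from the labels. The fit without the number is the main one, as planned before the data were examined, and the fit with it as a block is given where it changes a call or moves a count by more than 1.5 times. The arrays numbered 1 also stood apart technically: their E. coli and phage P1 spike controls had ratios of 2.23 to 2.43, against 0.921 to 1.08 in the other arrays.

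The rule for named genes was set before the data were examined. For each dose it took the 12 largest rises and 12 largest falls among probe sets with 1 symbol that passed the study threshold with the arrays of both groups not overlapping, which happens by chance in 10% of probe sets for 3 against 3; for the other contrasts it took 5 each. It also took up to 4 genes of each described list with the smallest p, and 13 genes in every case, of which HSPA1A had no probe set of its own. The study threshold was used because fewer than 20 genes passed the adjusted one. Genes named beyond that rule were chosen after their values were seen, as is said beside them.

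The code was tested on simulated data with the spread of the real probe sets. For the comparison of 100 mM with untreated over 54613 probe sets, limma's adjusted threshold recovered 1 of 50 probe sets changed 2-fold, 18 of 50 changed 4-fold, 28 of 50 changed 8-fold and 35 of 50 changed 16-fold. The study threshold recovered 21, 40, 44 and 47 of them, beside 464 false ones, against 6 false ones at the adjusted threshold. A simulated fall of 1 log2 unit in 1 list was found by camera, and 0 of the other 29 lists were called. The simulated genes were drawn independently, so this does not test camera for lists whose genes vary together. In the arrays the cell cycle list had an estimated correlation of 0.606. Alternatives tried were the block, median centring, quantile normalization, trended and robust moderation, array weights, 1 value per gene, a fit of only the 2 groups compared, an unmoderated test, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.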

Results

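Gene expression was measured in primary human bronchial epithelial cells, the lining cells of the large airways, after 24 h without ethanol, with 50 mM or with 100 mM ethanol. Each group had 3 arrays, and their number limits the precision. All values are log2 differences of ratios to the untreated median, so they tell how a gene differed between groups and not how strongly it was expressed. The title of the series speaks of biphasic effects of alcohol, and the design compares each dose with no ethanol.

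At 100 mM ethanol, genes of cell division were lower. All 24 genes of the cell cycle list had a negative difference, with a median of -1.67, and 22 of them fell when p was adjusted over the list alone. RRM2, a subunit of the enzyme that makes DNA building blocks, fell by 3.68 (SE 0.54, n = 3 per group, limma adjusted p over the list alone 0.00144). CDK1, the kinase that drives entry into mitosis, fell by 2.52 (SE 0.33, adjusted p over the list alone 0.00132). The replication helicase subunit MCM2 fell by 1.36 (SE 0.22) and the spindle motor KIF11 fell by 2.03 (SE 0.38). The 2 members that did not pass were CCNB2 and MCM6, at -0.09 (SE 0.27) and -0.54 (SE 0.39), named here because they are the exceptions.

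The list as a whole passed camera with the preset correlation of 0.01 (adjusted p = 4.43e-23). Its estimated correlation was 0.606, so the preset value takes its genes as far more independent than the arrays show. With an estimated correlation the list did not pass camera (adjusted p = 0.631 with an estimated correlation, and 0.419 with the block as well). By fry it did not pass without the block (adjusted p = 0.115) and passed with it (adjusted p = 0.0111). Adjusted over all genes, 0 of the 24 passed, and 6 passed with the block. Within replicate numbers 1, 2 and 3 the list's median difference at 100 mM was -2.07, -1.71 and -1.56, and without the 3 arrays numbered 1, whose spike controls stood apart, it was -1.61.

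**Figure D1:**
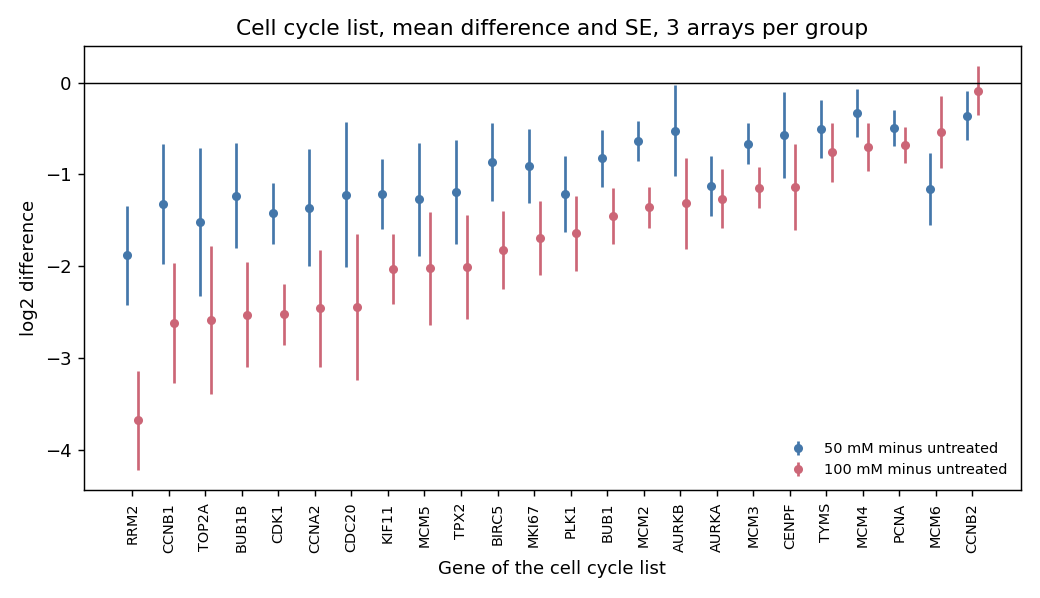
Log2 difference from untreated (vertical axis) of the 24 genes of the cell cycle list, ordered by the difference at 100 mM; points are the fitted means over 3 arrays per group and bars are standard errors. Every point lies below 0, with RRM2 lowest at -3.68 at 100 mM.

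Genes of the antioxidant response that the transcription factor NRF2 controls were higher at 100 mM. Of 23 measured, 21 had a positive difference, with a median of 0.35. OSGIN1, an oxidative stress-induced growth inhibitor, rose by 1.36 (SE 0.21, n = 3, limma adjusted p over the list alone 0.00464) and was the 1 member to pass; 7 passed with the block. SRXN1, GCLC and NQO1, which repair peroxiredoxins, make glutathione and reduce quinones, had differences of 0.65, 0.71 and 0.52. The list passed with camera's preset correlation (adjusted p = 5.17e-05), with an adjusted p = 0.631 with an estimated correlation.

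Genes of RNA splicing were slightly lower at 100 mM, with 20 of 23 below 0 and a median of -0.21. SRSF3 fell by 0.87 (SE 0.19) and SRSF7 fell by 0.79 (SE 0.18), both splicing factors of the SR family, and these 2 passed when adjusted over the list alone. After quantile normalization neither did, at -0.69 and -0.63. TRA2B and SRSF10 had differences of -1.06 and -0.55. Of 21 interferon-stimulated genes, 16 were above 0 with a median of 0.21, and 0 passed on their own over the list alone; OASL, RSAD2, OAS1 and OAS2 had differences of 0.52, 1.01, 0.67 and 0.34. Both lists passed camera with the preset correlation (adjusted p = 7.34e-04 and 0.0327), each with an adjusted p = 0.765 with an estimated correlation. Without untreated replicate 3 their medians were -0.12 and 0.14 and neither passed (adjusted p = 0.254 and 0.434), while without untreated replicate 1 they were -0.38 and 0.35 (adjusted p = 1.98e-05 and 0.0143). The interferon list also failed after quantile normalization (0.21, adjusted p = 0.0516), without the arrays numbered 1 (0.27, 0.0551), and without 100 mM replicate 1 (0.32, 0.0621) or replicate 2 (0.04, 0.367).

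In the list of inflammatory cytokines, 18 of 21 genes were below 0 at 100 mM. The neutrophil chemokine CXCL1 fell by 1.96 (SE 0.37, n = 3, limma adjusted p over the list alone 0.0136) and CXCL6 fell by 1.62 (SE 0.40, adjusted p over the list alone 0.0345), and these 2 passed when adjusted over the list alone, against 4 with the block. After quantile normalization neither passed, at -1.65 and -1.51. CXCL8 had a difference of -1.08 and IL6 of -0.64, while the monocyte and T cell chemokines CCL2 and CCL5 had 1.08 and 0.86. The list's median of -0.35 did not pass (adjusted p = 0.0756). It passed with the block (adjusted p = 0.00284, and adjusted p = 0.817 with an estimated correlation and the block), without untreated replicate 1 (-0.34, 0.0468) and without 100 mM replicate 2 (-0.55, 0.0151). With the block 8 of the 30 lists passed at 100 mM in place of 4, the others being cholesterol synthesis (median -0.21), oxidative phosphorylation (-0.14) and cell junctions (0.30). With an estimated correlation and the block 0 lists passed, these last 3 each with an adjusted p = 0.966 with an estimated correlation. Without the block, the cholesterol list passed without untreated replicate 1 (-0.30, 0.0295) and without 100 mM replicate 3 (-0.37, 0.00592), and oxidative phosphorylation without untreated replicate 2 (-0.21, 0.0334) and without 100 mM replicate 1 (-0.26, 0.00193). The number of lists passing was 7 without untreated replicate 1 and 2 without untreated replicate 3.

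In the fit without the block, with all 9 arrays, the lists for alcohol metabolism and for cell types did not pass at either dose. Medians of all lists that did not pass ran from -0.37 to 0.26 at 50 mM and from -0.35 to 0.34 at 100 mM. The alcohol and aldehyde metabolism list had medians of 0.02 at 50 mM and 0.01 at 100 mM. At 100 mM the medians were 0.11 for ciliated cells, -0.02 for club and goblet cells, -0.10 for basal cells, -0.17 for squamous cells, -0.08 for ionocytes and neuroendocrine cells, -0.17 for fibroblasts, 0.34 for leukocytes and 0.07 for endothelial cells. The leukocyte list passed without untreated replicate 1 at 50 mM (0.32, camera adjusted p = 0.00958) and 100 mM (0.43, 0.0392), and without the arrays numbered 1 at 50 mM (0.42, 0.0187). The squamous list passed without untreated replicate 2 at 50 mM (-0.49, 0.0393) and 100 mM (-0.41, 0.0334). These calls used the preset correlation; with an estimated correlation and all 9 arrays the adjusted p was 0.911 at 50 mM and 0.765 at 100 mM for leukocytes, and 0.911 and 0.997 for squamous cells. ADH7, the alcohol dehydrogenase of upper airway and stomach, had differences of -0.55 at 50 mM and -0.90 at 100 mM (SE 0.40, limma adjusted p 0.999 and 0.614 over all genes). At 100 mM ALDH1A1, ALDH2, ALDH3A1 and CYP2E1 had -0.21, 0.09, 0.15 and 0.34. The cilia regulator FOXJ1 had -0.55, the club cell protein SCGB1A1 -0.02, the mucin MUC5AC -0.25, the basal keratin KRT5 -0.02 and the haem oxygenase HMOX1 0.32. None of these 10 genes, nor CXCL8 or IL6, passed the adjusted threshold over all genes at either dose.

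Over single probe sets at 100 mM, 1 passed limma's adjusted threshold, a probe set of the muscle gene MYOZ2 that fell by 4.44 (SE 0.33, adjusted p 0.0474), while the 2 other probe sets of that gene had a mean difference of 0.68. It did not pass whichever 1 of the 9 arrays was left out. At unadjusted p under 0.05 there were 4092, and 6744 with the block. With 1 value per gene, GINS1, a part of the replication helicase, fell by 2.44 (SE 0.21, adjusted p 0.0353) as the 1 gene to pass. With the block as well, an alternative chosen after seeing the data, 65 genes passed, 60 lower and 5 higher; leaving out any 1 of the 9 arrays brought that count to 0.

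The study threshold was passed at 100 mM by 885 probe sets, 245 higher and 640 lower, of 620 genes. Unchanged groups simulated with independent arrays gave 470 on average and at most 533 in 100 simulations. The 3 other splits of these arrays that part all same-numbered pairs gave 264 to 288. Each of these splits mixes ethanol and untreated arrays within a group. A real change would then widen the spread and tend to lower the count, so they do not measure what chance gives. The largest falls by the naming rule were in single probe sets and included ESCO2 (-5.07, SE 0.71), which helps join sister chromatids, RRM2 (-4.32, SE 0.55), the condensin subunit NCAPH (-4.32, SE 0.80), the chromatin assembly factor CHAF1B (-3.31, SE 0.94), and TRIM4, ERICH3 and STAMBPL1 (-3.66, -3.47 and -3.32). The largest rises included the neuropeptide receptor NPY1R (3.80, SE 0.85), TWF1 (3.46, SE 0.68), LINC00950 (3.25, SE 0.48), EFCAB3 (3.22, SE 0.63), LINC00052 (3.15, SE 0.44) and RNF150 (2.88, SE 0.49). Among the 24 named, the adjusted p was 0.0474 for MYOZ2 and 0.198 or more for the others, and 15 passed the study threshold whichever array was left out; CHAF1B did so in 3 of the 9 cases. For all probe sets with a negative difference in genes with other probe sets, those others on average went the same way in 63.6%. Of 327 genes with a fall and other probe sets, with 1 called probe set counted per gene, this held for 82.3%. Among the named falls this held for 3 of 8, and the other probe sets of ESCO2, TRIM4 and ERICH3 had mean differences of -0.31, 0.12 and 0.38. Of 118 genes with a rise, 72.9% had other probe sets that went the same way, against 59.5% for all probe sets with a positive difference. Among the named rises this held for 5 of 8, and the other probe sets of TWF1 and RNF150 had mean differences of 0.18 and 2.20. The other probe sets of the 327 genes with a fall had a median change of -0.36, against -1.47 in the called ones. In 15.3% of these genes they fell 2-fold or more.

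**Figure D2:**
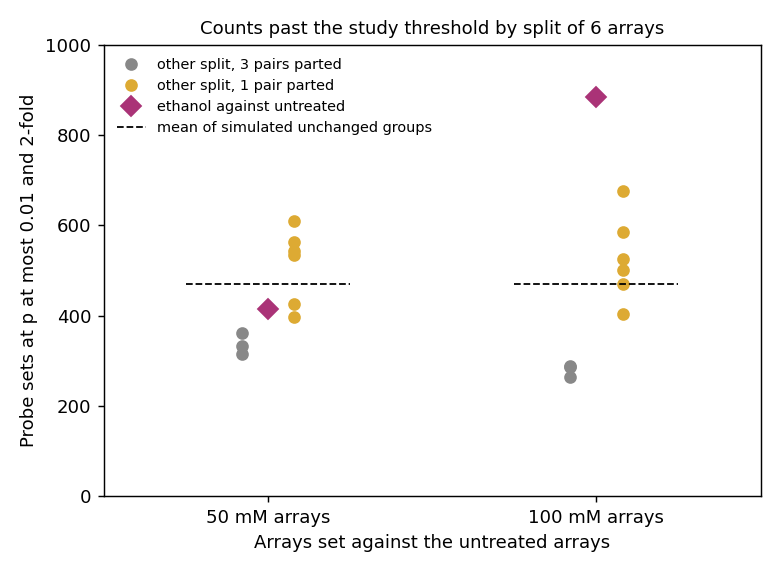
Number of probe sets with p of at most 0.01 and a 2-fold change (vertical axis) for the real split of 6 arrays (diamonds) and for the 9 other splits (circles), by how many same-numbered pairs a split parts. The dashed lines are the means of simulated unchanged groups; the count at 100 mM is 885 and that at 50 mM is 415.

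At 50 mM the cell cycle list had the same direction with a smaller size. The differences at both doses use the same untreated arrays, so the shared direction is not independent evidence. All 24 genes were below 0, with a median of -1.14. CDK1, RRM2, AURKA and KIF11 had differences of -1.42 (SE 0.33), -1.88 (SE 0.54), -1.12 (SE 0.33) and -1.21 (SE 0.38), and 0 members passed when adjusted over the list alone, against 18 with the block and 0 over all genes in either fit. Camera with the preset correlation gave the list an adjusted p = 7.37e-14, and it was 0.911 with an estimated correlation. Within replicate numbers 1, 2 and 3 the median was -1.004, -0.77 and -1.23. The splicing list had a median of -0.21, with SRSF7, SRSF3, HNRNPD and TRA2B at -0.49, -0.47, -0.61 and -0.57. Camera gave it an adjusted p = 0.0179, with an adjusted p = 0.911 with an estimated correlation. It did not pass after quantile normalization (-0.16, adjusted p = 0.0964), without untreated replicate 3 (-0.13, 0.849), or without 50 mM replicate 1 (-0.20, 0.0515) or replicate 2 (-0.24, 0.116).

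With the block 7 lists passed at 50 mM in place of 2, and 0 with an estimated correlation or by fry. Those added were the NRF2 list (median 0.11), interferon-stimulated genes (0.14), ribosomal proteins (0.09), leukocyte markers (0.26) and inflammatory cytokines (-0.37), with adjusted p = 0.884 for the interferon list and 0.957 for the others with an estimated correlation and the block. Without the block, leaving out 1 array moved some of these medians: the NRF2 list had -0.03 without 50 mM replicate 1 and 0.27 without 50 mM replicate 3 (adjusted p = 0.513 and 0.0480), the interferon list 0.00 without 50 mM replicate 2 and 0.28 without 50 mM replicate 3 (adjusted p = 0.781 and 0.00744), and the ribosomal list 0.38 without untreated replicate 1 (adjusted p = 0.00413). Without untreated replicate 1 the number of lists passing was 6, without untreated replicate 2 or 50 mM replicate 3 it was 4, and without untreated replicate 3 or 50 mM replicates 1 or 2 it was 1. In the list of inflammatory cytokines CXCL1, CXCL6, CCL5 and CXCL8 had differences of -1.46, -1.17, 1.05 and -0.89; 0 members passed when adjusted over the list alone and 3 with the block. MT1M, a metal-binding metallothionein, fell by 2.32 at 50 mM (SE 0.37, n = 3, limma adjusted p over its list alone 0.00154, over all genes 0.655) and differed by -0.20 at 100 mM. The other 6 metallothioneins were above 0 at 50 mM, among them MT1H, MT1F and MT1X at 0.31, 0.11 and 0.20, and their list did not pass (median 0.15, adjusted p = 0.783).

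**Figure D3:**
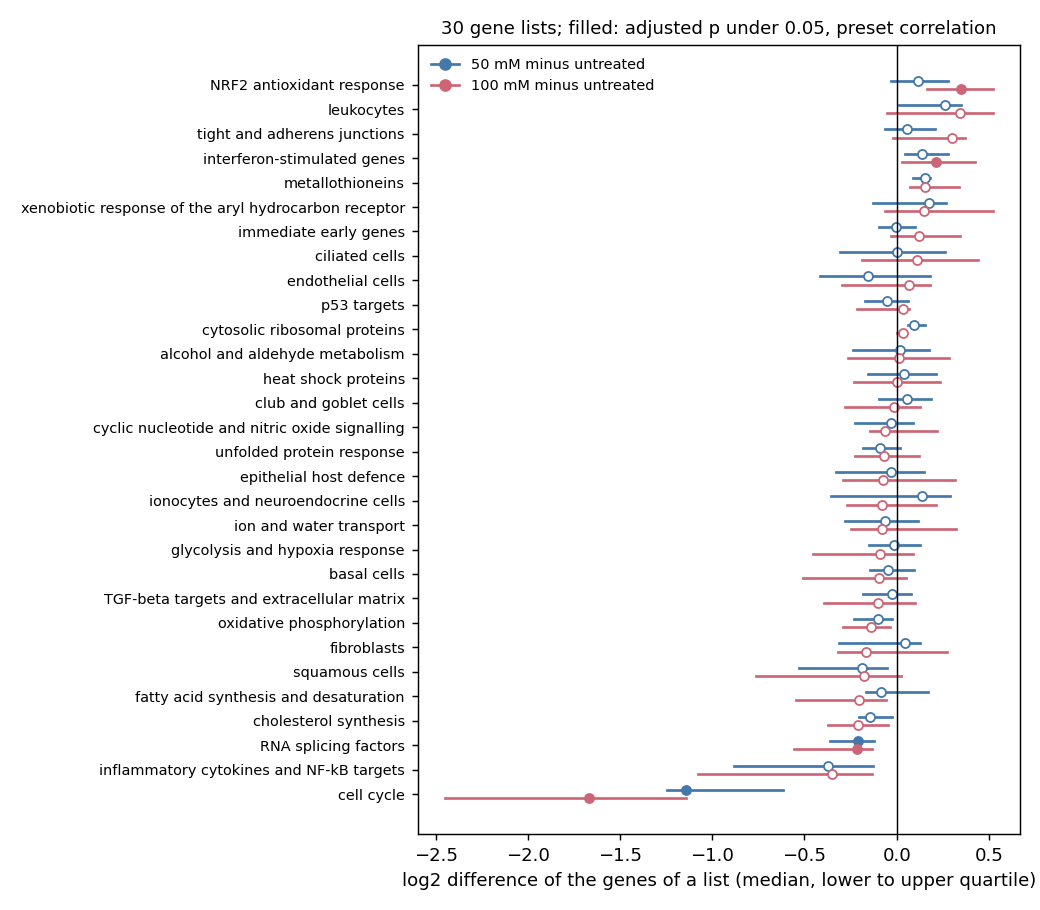
Median log2 difference (points) and lower to upper quartile (lines) of the measured genes of 30 lists at 50 mM and 100 mM, ordered by the median at 100 mM; filled points passed camera with the preset correlation. The cell cycle list lies lowest, at -1.14 and -1.67.

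No probe set passed limma's adjusted threshold at 50 mM, and 2682 had an unadjusted p under 0.05, where chance gives 2731; with the block it was 4640. The study threshold was passed by 415 probe sets, 151 higher and 264 lower, of 298 genes, and by 605 with the block. Unchanged groups simulated with independent arrays gave 469 on average, and the real 415 lay under that. The 3 other splits of these arrays that part all same-numbered pairs gave 316 to 362. They mix ethanol and untreated arrays within a group, which can lower their counts, so they do not measure what chance gives. Without the arrays numbered 1 it was passed by 715. The largest falls by the naming rule included probe sets of RBM46 (-3.71, SE 0.59), AMDHD1 (-3.68, SE 0.79), ENPP1 (-3.23, SE 0.73), the gap junction gene GJC1 (-3.13, SE 0.51), the histone deacetylase HDAC9 (-2.97, SE 0.53) and ESCO2 (-2.95, SE 0.71). The largest rises included PIK3C2A (4.32, SE 1.13), the viral RNA sensor IFIH1 (3.54, SE 1.02), HAPLN1 (3.47, SE 0.87), TFB2M (3.28, SE 0.80), INVS (3.15, SE 0.71) and TCF15 (2.98, SE 0.60). The adjusted p of the 24 named was 0.609 or more, 10 passed the study threshold whichever array was left out, and 21 passed it with the block. Of the rises given here IFIH1 passed it in 3 of the 9 cases, PIK3C2A and HAPLN1 in 5, TFB2M in 7, and INVS and TCF15 in 9. Of the falls given here ESCO2 passed it in 6, ENPP1 in 7 and the others in 9. PIK3C2A did not pass with the block, and the changes named were those of single probe sets. The other probe sets had mean differences of 0.11 for PIK3C2A, -0.18 for IFIH1, -0.23 for HAPLN1, 0.10 for TFB2M, -0.12 for INVS and 0.08 for HDAC9. Over all 24 named, they went the same way for 3 of 6 genes with a rise and 7 of 11 with a fall.

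Between the doses, the cell cycle list was lower at 100 mM than at 50 mM by a median of -0.77, with 22 of 24 genes below 0, and the NRF2 list was higher by 0.25. These list tests between doses were added after seeing the data. Camera gave adjusted p = 1.16e-10 and 0.00837 with the preset correlation, and both had an adjusted p = 0.941 with an estimated correlation. No probe set differed between the doses by limma's adjusted threshold. At unadjusted p under 0.05 there were 1779, where chance gives 2731, and 3121 with the block. The fit without the block leaves out the pairing by number and may be too strict here. Probe sets also share the arrays, so neither count measures a distance from chance. The 0 therefore does not show that the doses were alike. Between the doses 329 probe sets passed the study threshold. The 3 other splits of these arrays that part all same-numbered pairs gave 307 to 373. These splits mix the doses within a group, so they do not measure chance either. Single probe sets of RBM46 and VSTM2A differed between 100 mM and 50 mM by 4.01 (SE 0.59) and 3.53 (SE 0.64), and those of TRIM4, RALGPS1 and BAIAP2-DT by -3.71 (SE 0.49), -3.16 (SE 0.59) and -3.15 (SE 0.31). The other probe sets of these 5 genes had mean differences of 0.87, -0.06, 0.08, 0.33 and 0.27. Among the 10 named they went the same way for 1 of 2 genes with a higher value and 0 of 5 with a lower one. Of the 10 probe sets named for this contrast BAIAP2-DT had the smallest adjusted p, 0.109, and the next was 0.491. Without 50 mM replicate 3 the count past the adjusted threshold was 1.

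The bend asked whether the value at 50 mM lay off the mean of untreated and 100 mM, which does not need opposite directions at the 2 doses. None of the 30 lists had one by camera (smallest adjusted p 0.686); without untreated replicate 1 the count was 1 and without 100 mM replicate 1 it was 2. Of all probe sets 2 passed, both without a gene symbol, at 2.55 (SE 0.21) and -2.41 (SE 0.19), with a limma adjusted p of 0.0456 for each. An unadjusted p under 0.05 was found for 1626, where chance gives 2731. The group means of the 2 that passed, for untreated, 50 mM and 100 mM, were -0.01, 2.69 and 0.28 for the former and 0.10, -2.48 and -0.25 for the latter. The means of both doses thus lay on the same side of untreated. The SDs at 100 mM were 0.24 and 0.23 (n = 3), so a direction at that dose is not established. With the block 0 passed, with 2617 at unadjusted p under 0.05. The count was 2 without 50 mM replicate 3 and 0 when any of the 8 other arrays was left out. Single probe sets with a low value at 50 mM by the naming rule included those of RBM46 (-3.86, SE 0.51), VSTM2A (-3.20, SE 0.56) and HDAC9 (-3.06, SE 0.46), and those with a high value included TENM3 (2.40, SE 0.36) and IGF2BP2-AS1 (2.39, SE 0.28), with adjusted p of 0.317 or more over the 10 named. The other probe sets had mean bends of -0.18, -0.14 and -0.13 for RBM46, VSTM2A and HDAC9, and of 0.39 and -0.52 for TENM3 and IGF2BP2-AS1. They went the same way for 4 of 5 named genes with a low value and 1 of 4 with a high one. MT1M had a bend of -2.22 (SE 0.32, limma adjusted p over its list alone 7.65e-04) and did not pass over all genes. The F test found 0 probe sets that differed among the groups (smallest adjusted p 0.0921), with 3052 at unadjusted p under 0.05 where chance gives 2731.

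The overlap between the doses was compared with that of simulated unchanged groups. Of the probe sets past the study threshold 57 were higher at both doses, 94 lower at both and 1 opposite; independent sets would share 0.677, 3.09 and 2.95, and simulated unchanged groups with a common simulated control group had in common 46.9, 46.1 and 1.1 on average and at most 61, 60 and 5. The simulated groups passed 469 and 470 probe sets on average against the real 415 and 885, so these overlaps come from lists of other sizes and do not tell whether the real ones exceed chance. Nor do the simulations hold the pairing of arrays by number. ESCO2 was among those lower at both doses, and LINC00950 and TFB2M among those higher. Over all probe sets, which are not independent replicates, the differences correlated at r = 0.561, against 0.4999 in the simulations, with a covariance of 0.210 against 0.200. Both doses shared the control group in the simulations too, so 0.4999 already holds that part. What the excess comes from was not tested, since the simulations lack the pairing of arrays by number.

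As a measure of RNA quality, the 3-prime minus 5-prime log2 value of the actin and GAPDH control probe sets was 0.05 ± 0.09 (SD, n = 3) in untreated arrays, 0.00683 ± 0.00295 at 50 mM and 0.06 ± 0.12 at 100 mM. The exact two-sided permutation p was 0.7 for 50 mM and 0.9 for 100 mM against untreated, where the smallest that 3 against 3 can give is 0.1, so no difference could pass 0.05 and the test says nothing on whether RNA quality was alike. The ratio of the 18S ribosomal RNA control was 19.2, 5.29 and 63.9 in the untreated, 50 mM and 100 mM arrays numbered 1, and 0.423 to 1.01 in the other 6 arrays.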

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

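The 15 families of Affymetrix control probe sets lie outside the gene comparisons. In 1 of them, the trpn control for a bacterial gene, all 3 arrays at 100 mM lay above all 3 untreated arrays, with mean log2 ratios of 1.11 and 0.04 and a difference of 1.07. The lowest 100 mM array was at 0.57 and the highest untreated array at 0.52. Over the 30 comparisons of families with ethanol, chance would give 1.5 of this kind and 1 was found.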

How the results depend on the processing

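Chosen only after seeing the data were the fits without the arrays numbered 1, 1 value per gene with the block, and the alternatives for list medians. Not run were the filter on low level and the pseudocount, since a ratio holds no level; the mean of a gene's probe sets was already the gene value. The bend and the F test had no fit of 2 groups. The cause of the changes below was not tested. The count of 0 probe sets at 50 mM became 3 with array weights. The 1 at 100 mM became 0 with centring, quantile normalization, trended and robust moderation, the 2 groups alone or without the arrays numbered 1, 6 with array weights and 65 with 1 value per gene and the replicate block; leaving out 1 array gave 0 to 0. Between the doses leaving out 1 array gave 0 to 1. The 2 with a bend became 0 with the replicate block, quantile normalization, trended and robust moderation, 1 value per gene with or without the block, and without the arrays numbered 1, and 0 to 2 leaving out 1 array. The F test's 0 became 6 with array weights and 0 to 1 leaving out 1 array.

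The 415 past the study threshold at 50 mM became 227 with quantile normalization, 140 with trended and robust moderation, 206 with the unmoderated test (0 after Benjamini-Hochberg adjustment), 134 with 1 value per gene, 220 with the block as well (fewer units are tested) and 715 without the arrays numbered 1; leaving out 1 array gave 410 to 547. The 885 at 100 mM became 444, 392, 441 (0 after adjustment), 294 and 414 in the same settings, and 727 to 1028 leaving out 1 array. Quantile normalization gives all arrays the same spread, though the division by the untreated median had made the untreated arrays narrower. The trend was fitted on the mean log2 ratio, which is no level. The drops in these settings, and calls lost after quantile normalization, may therefore come in part from the form of the values.

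The 2 lists at 50 mM became 0 with an estimated correlation or fry, 7 with the replicate block, 1 with quantile normalization and 1 to 6 leaving out 1 array. The 4 at 100 mM became 0 with an estimated correlation or fry, 8 with the replicate block and 2 to 7 leaving out 1 array. The 0 with a bend became 0 to 2 leaving out 1 array. The cell cycle medians of -1.14 and -1.67 stayed the same but did not pass with an estimated correlation or fry. Leaving out 1 array they ran from -1.30 to -0.79 and from -2.004 to -1.37. They passed throughout with the preset correlation (largest limma camera adjusted p 4.45e-07 and 3.63e-17), which is far below the 0.606 estimated for this list. The correlation of the 2 doses ran from 0.479 to 0.667 leaving out 1 array. With the replicate block PIK3C2A, SYCE1L and CRLS1 at 50 mM, MCF2L2 and PDE1C at 100 mM and the bend of SYCE1L did not pass the study threshold; beyond these and the calls given with the block in the results it changed no call described here. Of the values of named single genes (with left-out arrays counted once, at the value nearest 0) and of the NRF2, splicing and interferon lists, 492 kept their direction and side of the threshold under an alternative, 60 fell below it, 19 passed it, 21 without a call changed sign, and 0 with a call changed sign.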

Other observations

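The tests of the cell cycle pattern and the fit with 1 value per gene and the replicate block were chosen only after the results were seen. With that fit 65 genes passed limma's adjusted threshold at 100 mM. The genes named here were chosen after their values were seen. Of the 65 genes 6 belong to the cell cycle list, and no enrichment of any function among the others was tested. Others were the kinetochore protein NDC80 (-2.95, SE 0.21), HJURP (-2.53, SE 0.18), which deposits the centromere histone, the kinesin KIFC1 (-2.97, SE 0.33), the replication factor MCM10 (-2.50, SE 0.23), and CDC6 (-1.90, SE 0.20), which helps load the replication helicase. The alarmin IL33 was at -2.16 (SE 0.18), beside CXCL1 and CXCL6. The 5 higher genes were LINC00052 (3.15), RNF150 (2.37), PCOLCE (2.21), PRKAG2-AS1 (1.96) and RNF112 (1.68). Their adjusted p ran from 0.0353 to 0.0488, so the genes passed narrowly, and leaving out any 1 of the 9 arrays gave 0 genes. At 50 mM 64 of the 65 had the same sign and all 65 a smaller size, with a median of -1.22 against -1.96. These values share the untreated arrays, which favours the same sign. The genes were also chosen by their difference at 100 mM in these arrays, which favours a smaller size at 50 mM. The comparison is therefore no test of a dose response.

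Lower cell cycle genes at 100 mM could come from array scaling, from the arrays numbered 1, from degraded RNA or from fewer basal cells. After quantile normalization the list's median was still -1.55, and within replicate numbers 2 and 3 the value nearer 0 was -1.56, which argues against the first pair. The 3-prime minus 5-prime value differed by 0.00797 between 100 mM and untreated arrays, with SDs of 0.12 and 0.09 (n = 3). Judged by the actin and GAPDH controls alone, this argues against marked degradation at 100 mM and leaves smaller differences open. The basal cell list, with 13 of 18 genes measured, shares 0 genes with the cell cycle list. Its median was -0.10 beside the cell cycle list's -1.67, which argues against a loss of basal cells in general as the whole cause. A loss of only the dividing cells among them might not show in this list. A candidate explanation that stays open is less cell division with ethanol; it is a hypothesis, since no cell counts were analysed here and the list did not pass camera with an estimated correlation, though it passed fry with the block.

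Falls past the study threshold at 100 mM are unlikely to be noise of single probe sets alone. Other probe sets of the same genes went the same way for 82.3% of genes (95% exact interval 77.7% to 86.3%). For all probe sets with a negative difference in genes with other probe sets the share was 63.6%. Here and below, the called share counts 1 probe set per gene and the share set against it counts every probe set. The interval takes the genes as independent, though they share the arrays. The other probe sets had a median change of -0.36 against -1.47 in the called ones, and in 15.3% of genes they fell 2-fold or more. The direction was thus shared more than the size. For rises at 100 mM the share going the same way was 72.9% (63.9% to 80.7%) against 59.5%, which leaves noise open. At 50 mM it was 67.9% (59.4% to 75.6%) against 65.0% for falls, which also leaves it open. For rises at 50 mM it was 50.6% (39.0% to 62.2%) against 51.1%, what noise of single probe sets would give.

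Other splits of the arrays were tested as well. The 10 splits of 6 arrays are too few for a share under 0.05. At 100 mM, 1 of 10 splits reached the 885 probe sets past the study threshold, the real one, with 677 as the highest other and 288 among splits that part all 3 same-numbered pairs. At 50 mM, 6 of 10 reached the real 415, with 610 as the highest other and 362 among those that part all 3 pairs. For adjusted calls, 10 of 10 splits reached the 0 of 50 mM, with 2 as the highest other and 1 among those that part all 3 pairs. At 100 mM 6 of 10 reached the real 1, with 2 as the highest other and 0 among those that part all 3 pairs. Between the doses 10 of 10 reached the 0, with 3 as the highest other and 0 among those that part all 3 pairs. Any split reaches a count of 0, so 10 of 10 was fixed in advance at 50 mM and between the doses. For lists, 8 of 10 splits reached the 2 of 50 mM and 6 of 10 the 4 of 100 mM, with 10 as the highest other for each, and 4 and 2 among those that part all 3 pairs. The highest other counts came from splits that part 1 pair and keep the other pairs together, so they follow the replicate numbers in part. All the other splits mix the 2 compared groups. A real change would then widen the spread and tend to lower their counts, so they do not measure what unchanged arrays would give. Of the 4 splits within the replicate numbers, 1 reached the 65 genes of the block, the real one, with 0 as the highest other. The 4 are too few for a share under 0.05. Each other split swaps untreated and 100 mM within 1 replicate number, so a real change would enter the residual spread. The 65 passed narrowly, so a count of 0 in those splits was likely in any case.

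For the bend and the F test 100 splits of the 9 arrays were used, the real one included. For the bend 18 of 100 gave 2 or more probe sets, so chance is not excluded, and the highest other gave 2051. The real split keeps 0 same-numbered pairs together, while most others that reached 2 keep 2 or more together and so differ from it in this. For the F test 100 of 100 reached the real 0, with 570 as the highest other, and for lists with a bend 100 of 100 reached the real 0, with 11 as the highest other. Any split reaches a count of 0, so these shares were fixed in advance and decide nothing. The split with 2051 kept 5 of the 9 same-numbered pairs together, which points to a structure of the arrays by replicate number.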
